A study of Mus musculus with 9 samples.

How the data were processed

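Kidneys of C57BL/6 mice were profiled by bulk RNA sequencing in 3 groups of 3 biological repeats: saline sham, day 3 and day 7 after a single intraperitoneal dose of cisplatin (20 mg/kg). Per the labels, RNA was extracted with TRIzol, samples had an RNA integrity number above 7.0, 2 µg of RNA went into a directional NEB library kit, and sequencing was on an Illumina HiSeq. The deposited values are FPKM per gene and library, made by the authors and rounded to 2 decimals, per the file headers and the values themselves. HISAT, StringTie, FastQC 0.10.1 and the GRCm38 build are named in the submitters' processing notes, without a role or an order. The aligner's settings, the annotation release, filters and the strand setting are not given in the sources used here, so reads of overlapping and antisense genes could not be told apart. Read counts were not used here, since the files hold FPKM, so read depth is unknown, no counting interval or detection floor could be given, and a value of 0 means only listed at 0. FPKM is scaled within a library, so a rise in abundant transcripts lowers the values of all others.

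Gene IDs were matched to GENCODE M21, which gave a symbol for 55144 of them and none for 241, and coordinates are those of that annotation on GRCm38. Genes with at least 1 FPKM in at least 3 of the 9 libraries were tested (13718). Values were taken as log2(FPKM + 1), on which fold changes of weakly expressed genes are understated. A limma model (version 3.58.1 in R 4.3.3) with the 3 groups and no other term was fitted to all 9 libraries, so that the groups share the estimate of the spread, with eBayes and a mean-variance trend. The 3 contrasts were day 3 against sham, day 7 against sham and day 7 against day 3, each two-sided with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Errors of group means are SD over 3 libraries and errors of log2 fold changes are standard errors from limma.

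These comparisons, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. There were 43 gene lists, written from general knowledge of kidney segments, cisplatin injury, cell death, immune cells, matrix, metabolism and sample checks. They hold 961 distinct genes, of which 960 matched an ID and 790 were tested. The 40 lists with at least 5 tested members were tested with limma's camera at an inter-gene correlation of 0.01 and adjusted over the lists, and again with the correlation estimated per list. Camera compares a list with all other genes, so a list's direction is relative to them. Members called were counted with adjustment over all genes and over the list alone. Named genes were, for each comparison, the 5 largest changes each way among called genes without overlap between the groups and with a group mean of at least 5 FPKM, up to 3 called members of each list with a group mean of at least 1 FPKM from the largest down, and 15 genes of kidney injury and cisplatin handling, 2 of which stayed below the filter. Predicted genes, pseudogenes by symbol and immunoglobulin or T cell receptor segments were left out of the first part. Of the genes that the rule names, 1 is not reported here.

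The alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median-of-ratios scaling, quantile normalization, robust variance, the 6 libraries of a contrast alone, the replicate number as a block, a 2-fold minimum, fry in place of camera and leaving out each library in turn. A correction for GC content and length, protein-coding genes only and removal of transcripts under 200 nt were added after the data were seen. In the correction, a natural spline with 5 degrees of freedom on GC content and another on log10 length of the longest transcript were fitted and removed in each library, over the 13707 tested genes with a value. Agreement of the 2 responses to cisplatin was set against 100 simulated pairs of unchanged groups sharing the sham libraries. The gene test was tested on simulated data for 13718 genes with 200 changed genes. For day 3 it recovered 40% of 2-fold and 76% of 4-fold changes with 7 false calls, and for day 7 it recovered 35% and 75% with 5 false calls. A GC content trend imposed on that simulation gave 3378 and 3312 false calls, and 7 and 5 after the correction. The imposed trend was linear and the same in each library of the group, a shape that the spline can fit, so its removal was built in. Changed genes were drawn without regard to GC content. The simulation thus cannot show how the correction treats real changes that go with GC content. In a simulation of the list test for day 3, 1 shifted list was called and 0 of the others.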

Results

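Gene expression was measured by bulk RNA sequencing of kidneys from C57BL/6 mice in 3 groups of 3 biological repeats: sham animals given saline, animals killed 3 days after 1 intraperitoneal dose of cisplatin, and animals killed 7 days after it. Cisplatin is a platinum drug that crosslinks DNA and injures the kidney tubule, and the dose was 20 mg/kg. Each of the 9 libraries was deposited as FPKM, fragments per kilobase of transcript scaled to the mapped fragments of the library, for every annotated gene. The FPKM summed to between 421810 and 509537 per library, and 11647 to 13183 genes reached 1 FPKM. Read depth is unknown because the deposited values hold no counts, so no counting interval is given. Transcripts encoded by mitochondrial DNA took 25.6% to 27.3% of the FPKM in sham, 27.1% to 31.8% at day 3 and 31.7% to 32.6% at day 7. Correlations of log2(FPKM + 1) within a group were 0.948 to 0.977 in sham, 0.942 to 0.972 at day 3 and 0.973 to 0.980 at day 7. The design asks how the renal transcriptome differs between an earlier and a later phase of acute kidney injury.

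**Figure D1:**
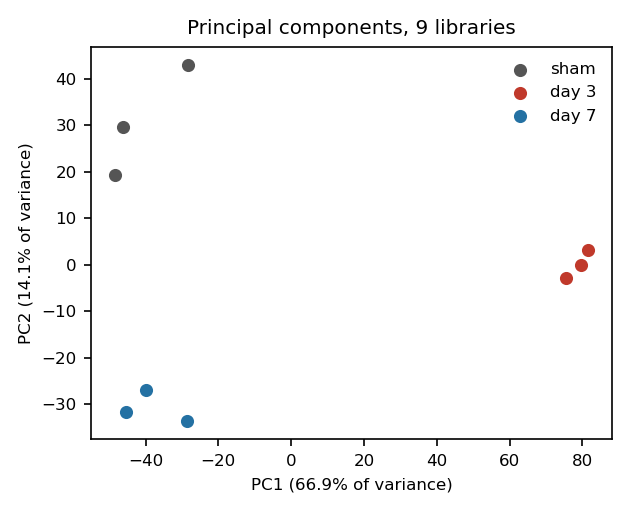
Each point is 1 of the 9 libraries, placed by the first 2 principal components of log2(FPKM + 1) over the tested genes (axes in component units, share of variance in the labels). The first component (66.9%) parted the 3 day 3 libraries from the other 6, and the second (14.1%) parted sham from day 7.

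The genes fixed as a check of the labels were read first in every library. Havcr1 (chromosome 11, 46735080 to 46779578), which encodes the tubule injury protein KIM-1, stood at 8.29, 35.45 and 1.5 FPKM in the sham libraries, 402.12, 141.44 and 163.26 at day 3, and 1.04, 58.22 and 1.45 at day 7. Lcn2 (chromosome 2, 32384633 to 32388252), which encodes the injury marker NGAL, was at 14.88, 2.97 and 1.17 FPKM in sham, 556.28, 743.34 and 381.11 at day 3, and 2.31, 10.09 and 1.59 at day 7. Cdkn1a (chromosome 17, 29090976 to 29100727), the p53 target that encodes the cell cycle inhibitor p21, was at 12.21, 3.8 and 5.64 FPKM in sham, 262.56, 295.84 and 287.95 at day 3, and 5.44, 9.11 and 3 at day 7. Slc34a1 (chromosome 13, 55398187 to 55415592), the phosphate transporter of the proximal tubule, was at 393.54, 987.55 and 1051.23 FPKM in sham, 9.83, 37.32 and 45.43 at day 3, and 587.23, 497.57 and 619.68 at day 7. All coordinates are on GRCm38.

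**Figure D2:**
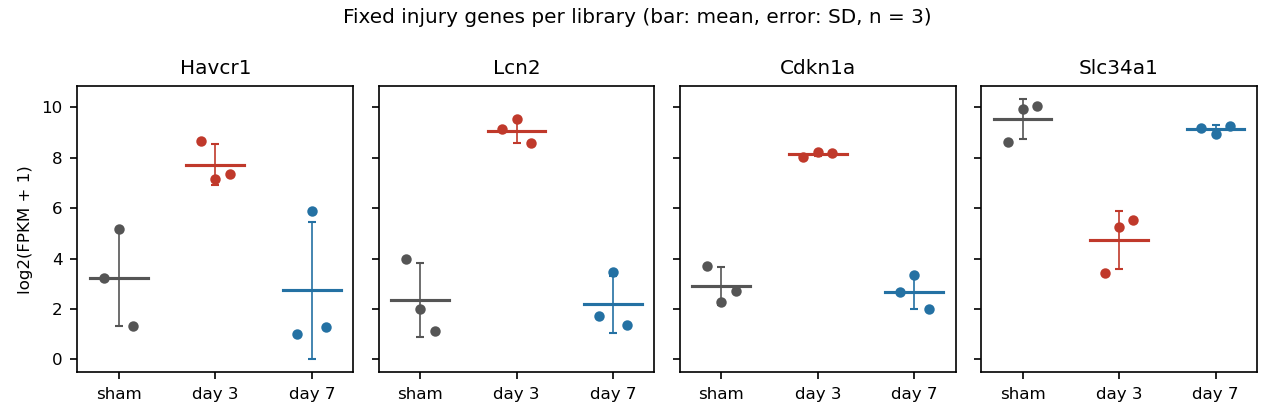
Points are single libraries on a log2(FPKM + 1) axis for sham, day 3 and day 7, with the group mean (bar) and SD (error, n = 3). The day 3 libraries lay above all others for Havcr1 (141.44 FPKM or more), Lcn2 and Cdkn1a and below all others for Slc34a1 (45.43 FPKM or less).

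At day 3 the kidney had lost much of its proximal tubule, loop and collecting duct expression and had gained tubule injury, p53 target, stress and neutrophil transcripts. Krt20, a keratin of injured tubule cells, rose from 0.403 ± 0.320 to 650 ± 52.9 FPKM (SD, n = 3; log2 fold change 8.88 ± 0.41 SE, adjusted p = 2.32e-06, limma). Nat8, an acetyltransferase of the proximal tubule, fell from 241.9 ± 54.4 to 7.06 ± 1.28 FPKM (log2 fold change -4.90 ± 0.22, adjusted p = 2.32e-06). Of 13718 genes tested, 8214 differed from sham, 5389 higher and 2825 lower, and 3631 of them by at least 2-fold (2347 higher, 1284 lower).

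Tubule injury markers were higher. Of 32 tested tubule injury and repair markers 28 were higher and none lower (29 higher when adjusted over the list alone), with a median log2 fold change of 2.38 (camera adjusted p = 1.02e-06, and adjusted p = 0.558 with an estimated correlation). Lcn2 rose by 6.71 ± 0.75 on the log2 scale (adjusted p = 0.000107), and Sprr2f, a small proline-rich protein listed at 0 in all 3 sham libraries, was at 262.4, 186.99 and 150.61 FPKM. Outside the list, the protease inhibitor Slpi rose from 0.137 ± 0.080 to 72.5 ± 8.19 FPKM and Sprr2g from 0.180 ± 0.105 to 69.7 ± 18.2 FPKM. Havcr1 rose by 4.48 ± 1.35 (adjusted p = 0.0186), a call lost without sham 3 (adjusted p = 0.0661) or day 3 library 1 (adjusted p = 0.0603). Spp1, which encodes osteopontin, went from 432 ± 211 to 8571 ± 2312 FPKM (log2 fold change 4.38 ± 0.49).

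Genes of the DNA damage response rose with them. Among 33 p53 target genes 29 were higher and 1 lower, the same numbers as when adjusted over the list alone, with a median of 2.24 (camera adjusted p = 2.84e-09, and adjusted p = 0.480 with an estimated correlation). Cdkn1a rose by 5.24 ± 0.40, Trp53inp1 by 4.75 ± 0.20, Btg2 by 4.28 ± 0.25 and Mdm2, the ubiquitin ligase that limits p53, by 3.06 ± 0.18. In the DNA repair list 7 of 16 tested genes were higher and 1 lower, and the list was not called (camera adjusted p = 0.197). Ercc1 (3.31 ± 0.14) and Ercc5 (2.24 ± 0.16), both of nucleotide excision repair, were its largest changes. Among 23 DNA replication genes 12 were higher, led by Rrm2 (2.29 ± 0.34), Cdt1 and Pcna (camera adjusted p = 0.0356, and adjusted p = 0.605 with an estimated correlation). That call was lost without sham 1 (adjusted p = 0.0810), without sham 3 (adjusted p = 0.0583) and with quantile normalization (adjusted p = 0.0572). Only 8 of 30 genes of mitosis and cell division were expressed enough to be tested, and 4 were higher (camera adjusted p = 0.276). Mki67, a proliferation marker below the expression filter, was at 0.06, 0.4 and 0.17 FPKM in sham and 0.49, 0.31 and 0.5 at day 3.

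Transport and metabolism genes of the proximal tubule were lower. In the proximal tubule transport list 32 of 37 genes were lower and none higher, also when adjusted over the list alone, with a median of -2.81 (camera adjusted p = 5.91e-18, and adjusted p = 0.318 with an estimated correlation). Slc34a1 fell by 4.79 ± 0.55 on the log2 scale, and Slc22a2, the organic cation transporter that takes up cisplatin, went from 151.5 ± 30.7 to 7.99 ± 1.0 FPKM (log2 fold change -4.07 ± 0.19, adjusted p = 2.44e-06). The proximal tubule metabolism list had 30 of 34 genes lower and 1 higher, again the same over the list alone, with a median of -2.68 (camera adjusted p = 1.17e-14, and adjusted p = 0.318 with an estimated correlation). Its leading members after Nat8 were G6pc, the glucose-6-phosphatase of gluconeogenesis (139.2 ± 96.4 to 3.11 ± 0.39 FPKM), and Ttc36 (578 ± 118 to 25.3 ± 13.9 FPKM). Nat8f6 and the steroid dehydrogenase gene Hsd3b4 were lower as well (log2 fold changes -4.89 ± 0.49 and -4.75 ± 0.33).

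Nuclear genes of mitochondrial energy metabolism were lower by smaller amounts, and mitochondrially encoded genes went both ways. Of 40 nuclear genes of oxidative phosphorylation 34 were lower and none higher (35 lower adjusted over the list alone), with a median of -0.77 (camera adjusted p = 1.66e-13, and adjusted p = 0.342 with an estimated correlation), led by Ndufs8 (-1.57 ± 0.14) and Ndufs7 (-1.50 ± 0.16). The tricarboxylic acid cycle list had 15 of 20 genes lower (15 lower and 1 higher adjusted over the list alone; camera adjusted p = 7.50e-07, and adjusted p = 0.342 with an estimated correlation), led by Pcx (-2.65 ± 0.24). In fatty acid oxidation and peroxisome 17 of 41 were lower and 2 higher (16 and 2 adjusted over the list alone; camera adjusted p = 2.81e-05, and adjusted p = 0.558 with an estimated correlation). Its median against the sham mean was 0.02 in day 3 library 1, and -0.82 and -0.84 in libraries 2 and 3. Its largest change was a rise, of Pdk4 (3.25 ± 0.80), a kinase that holds back pyruvate oxidation, followed by a fall of the peroxisomal oxidase Acox2 (-2.56 ± 0.16). Among the 13 mitochondrially encoded genes 6 were lower and 2 higher, and mt-Cytb fell by 0.91 ± 0.14 (camera adjusted p = 0.0356, and adjusted p = 0.605 with an estimated correlation). The most abundant of them, mt-Co1, rose from 24117 ± 625 to 39664 ± 7280 FPKM (0.70 ± 0.17, adjusted p = 0.00590). Its call was lost under median-of-ratios scaling (adjusted p = 0.101) and after removal of a GC content trend (adjusted p = 0.0573). The call on the mitochondrially encoded genes was lost without sham 1 (adjusted p = 0.0627), without day 3 library 1 (adjusted p = 0.134) and with quantile normalization (adjusted p = 0.700).

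Every nephron segment list beyond the proximal tubule was lower as well. Thick ascending limb markers were lower in 13 of 14 genes (14 adjusted over the list alone; median -1.94, camera adjusted p = 2.32e-07, and adjusted p = 0.342 with an estimated correlation). Egf stood at -3.52 ± 0.45 and Umod, which encodes uromodulin, at -2.49 ± 0.45. Distal convoluted and connecting tubule markers were lower in 10 of 14 and higher in 1 (median -2.02, camera adjusted p = 2.01e-05, and adjusted p = 0.342 with an estimated correlation). Among them the thiazide-sensitive cotransporter gene Slc12a3 fell furthest (39.8 ± 9.16 to 2.11 ± 0.64 FPKM). Principal cell markers of the collecting duct were lower in 8 of 14 (camera adjusted p = 0.000216, and adjusted p = 0.558 with an estimated correlation). Hsd11b2 changed most (-3.78 ± 0.64). Intercalated cell markers were lower in 11 of 16 and higher in 1 (camera adjusted p = 1.16e-05, and adjusted p = 0.495 with an estimated correlation). The ammonia channel gene Rhcg fell furthest (72.4 ± 18.9 to 1.93 ± 0.998 FPKM). Counts adjusted over the list alone were the same for these last 3 lists. Podocyte markers were lower in 5 of 13 and higher in 1 (4 and 1 adjusted over the list alone; camera adjusted p = 0.0356, and adjusted p = 0.605 with an estimated correlation), a call that the podocyte markers lost without sham 1 (adjusted p = 0.0859) or day 3 library 1 (adjusted p = 0.137).

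Heat shock and immediate early genes were higher in 16 of 21 and lower in 1, also over the list alone (median 2.00, camera adjusted p = 0.00121, and adjusted p = 0.558 with an estimated correlation). Fosl1, a subunit of AP-1, rose from 0.043 ± 0.075 to 33.0 ± 4.30 FPKM. NRF2 target genes, which answer oxidative stress, were higher in 15 of 23 and lower in 1 (camera adjusted p = 0.0138, and adjusted p = 0.605 with an estimated correlation). Srxn1, which encodes sulfiredoxin, rose most (4.40 ± 0.62). Apoptosis genes were higher in 16 of 26 and lower in 2 (18 and 2 adjusted over the list alone; camera adjusted p = 0.00784, and adjusted p = 0.569 with an estimated correlation). Pmaip1, which encodes NOXA, rose by 4.17 ± 0.40. The necroptosis kinase Ripk3 rose from 0.453 ± 0.200 to 4.38 ± 0.24 FPKM and its substrate Mlkl from 0.540 ± 0.070 to 9.43 ± 3.05 FPKM, and 9 of the 16 tested genes of necroptosis and pyroptosis were higher (camera adjusted p = 0.0554, not called). That list was called under median-of-ratios scaling (adjusted p = 0.0347), with quantile normalization (adjusted p = 0.0496), without sham 3 (adjusted p = 0.0389) and without day 3 library 2 (adjusted p = 0.0319). Gpx4, the enzyme that removes lipid peroxides, fell from 539 ± 35.7 to 235 ± 44.7 FPKM (-1.21 ± 0.15), while Acsl4 rose by 2.98 ± 0.28, and 14 of 26 ferroptosis and glutathione genes were higher with 6 lower (camera adjusted p = 0.593, not called). Slc7a11, the cystine transporter, stayed below the filter at 0.03, 0.02 and 0 FPKM in sham and 0.49, 0.52 and 0.59 at day 3. In the list of cisplatin transport and detoxification, 9 of 16 were lower and 5 higher (camera adjusted p = 0.00950, and adjusted p = 0.375 with an estimated correlation), a call lost with quantile normalization (adjusted p = 0.0807). Its metal-binding metallothioneins Mt2 and Mt1 rose by 5.07 ± 0.52 and 3.60 ± 0.40, while the copper transporter Slc31a1 fell by 0.75 ± 0.14.

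Genes of protein synthesis and turnover were mostly higher, and more genes of cholesterol synthesis and uptake were lower than higher. Of 40 cytosolic ribosomal proteins 36 were higher (37 over the list alone, median 0.75, and 0.46 under median-of-ratios scaling, camera adjusted p = 1.49e-06, and adjusted p = 0.569 with an estimated correlation). Rps27a rose most (60.1 ± 5.89 to 158 ± 10.9 FPKM). Proteasome genes were higher in 23 of 30 (camera adjusted p = 0.000247, and adjusted p = 0.558 with an estimated correlation), led by Psmc6 (1.63 ± 0.11). Cholesterol synthesis and uptake genes were lower in 9 of 21 and higher in 3 (camera adjusted p = 0.00950, and adjusted p = 0.605 with an estimated correlation), led by Cyp51 (-2.16 ± 0.24). The call on cholesterol synthesis and uptake was lost without sham 2 (adjusted p = 0.0834). The median of this list against the sham mean was -0.42 to -0.37 in the day 3 libraries. It was -0.47, 0.44 and 0.11 in sham libraries 1, 2 and 3. In the endoplasmic reticulum and integrated stress response list 10 of 26 were higher and 4 lower, with Atf3 at 3.97 ± 0.29 and Herpud1 at -2.23 ± 0.39, and the list was not called (camera adjusted p = 0.621). In glycolysis 5 of 17 were higher and 7 lower (median -0.19, and 0.06 after removal of a GC content trend; camera adjusted p = 0.155, not called).

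Among immune cell markers, the tested ones of neutrophils rose together and those of macrophages parted. Of 16 neutrophil markers 6 were expressed enough to be tested. All 6 were higher, also over the list alone (median 2.53, camera adjusted p = 0.0256, and adjusted p = 0.569 with an estimated correlation). A marker low in sham can pass the filter through its day 3 values alone, which favours rises among those tested. S100a8 went from 1.72 ± 1.38 to 18.9 ± 13.6 FPKM, and Lcn2 belongs to this list as well as the injury list. Of 17 macrophage and monocyte markers 4 were higher, 4 lower and 9 not called, and the list was not called (median 0.06, and -0.10 under median-of-ratios scaling; mean 0.65, camera direction down, adjusted p = 0.777). Chil3 rose by 5.54 ± 0.49, Cd68 by 4.21 ± 0.24 and Cd14 by 3.36 ± 0.32 on the log2 scale, while Eif4a1, the gene next to Cd68, was at 1.34. Csf1r, the receptor that macrophages need to survive, and the chemokine receptor Cx3cr1 were lower (log2 fold changes -1.53 and -0.97), and these 3 last genes were named after their values were seen. The class II genes Cd74, H2-Ab1 and H2-Aa fell (log2 fold changes -2.90 ± 0.55, -2.36 ± 0.50 and -2.32 ± 0.44). They belong to an antigen presentation list that had 4 of 14 higher and 5 lower and was not called (median 0.29, and -0.01 under median-of-ratios scaling; mean -0.41, camera direction down, adjusted p = 0.283).

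Cytokine and interferon genes were mostly higher. TNF and NF-kB response genes were higher in 12 of 16 and lower in 1 (13 and 1 over the list alone; camera adjusted p = 0.00649, and adjusted p = 0.571 with an estimated correlation). Cxcl1, a neutrophil chemoattractant, rose most (1.15 ± 0.82 to 37.8 ± 17.4 FPKM). Interferon-stimulated genes were higher in 22 of 25 (median 1.48, camera adjusted p = 2.01e-05, and adjusted p = 0.558 with an estimated correlation), led by Oasl1 (3.11 ± 0.35). In the lists of chemokines and cytokines, of complement, and of endothelial markers, 10 of 17, 2 of 15 and 1 of 18 were higher and 1, 4 and 4 lower, and none was called (camera adjusted p = 0.0971, 0.295 and 0.155). Adjusted over the list alone, chemokines had 10 higher and 2 lower, complement 2 and 1, and endothelial markers 1 and 2. The endothelial median was 0.04, and -0.22 under median-of-ratios scaling, and the mean was -0.12. Chemokines and cytokines were called under median-of-ratios scaling (adjusted p = 0.0382) and with quantile normalization (adjusted p = 0.0434), and endothelial markers without day 3 library 3 (adjusted p = 0.0182). Extracellular matrix and fibroblast activation genes were higher in 14 of 33 (11 adjusted over the list alone; camera adjusted p = 0.0915, not called). The list of extracellular matrix and fibroblast activation was called under median-of-ratios scaling (adjusted p = 0.0316), with quantile normalization (adjusted p = 0.0377), after removal of a GC content trend (adjusted p = 0.0444) and without day 3 library 1 (adjusted p = 0.00712). Col1a1, a main collagen chain, was at 3.27 ± 1.24 FPKM in sham and 5.57 ± 3.31 at day 3 (adjusted p = 0.324). Erythrocyte genes were lower in 5 of 6 (median -3.28, camera adjusted p = 0.00881, and adjusted p = 0.495 with an estimated correlation). Hba-a2, a globin gene, was at 31.5 ± 4.21 FPKM in sham and 1.70 ± 0.94 at day 3.

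Reads of Sprr2f, Sprr2g, Nat8, Nat8f6, the globins and the ribosomal protein genes can also map to near-identical copies or pseudogenes, so their values are uncertain. The libraries of day 3 and sham did not overlap for 64.0% of tested genes, against 10% by chance, and 25 of 40 gene lists were called (11 up, 14 down), none of them with an estimated correlation. Rescaling by the median of ratios moved the median of all genes by -0.22 (log2) and the split of called genes to 4083 higher and 3951 lower.

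**Figure D3:**
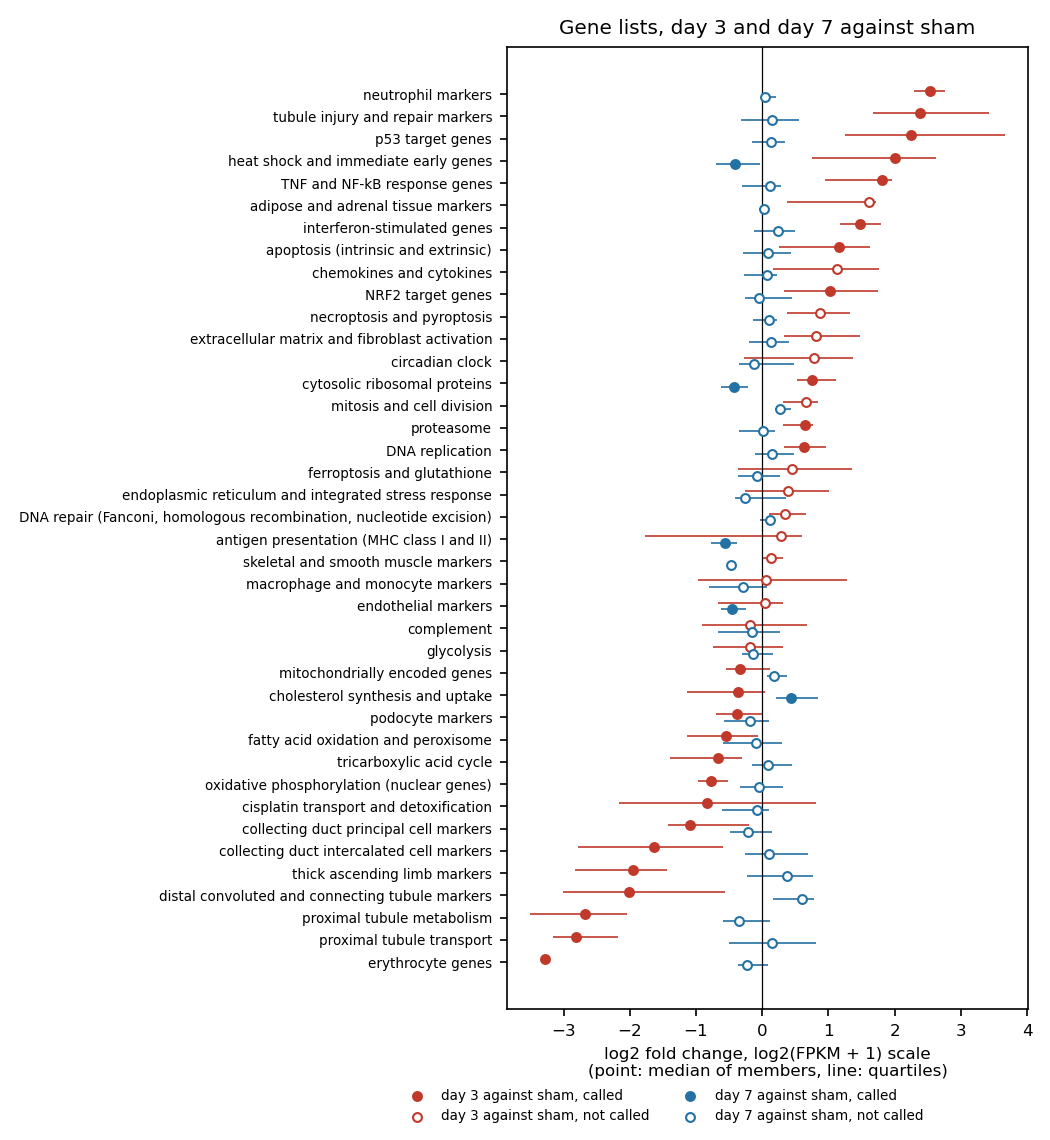
Median log2 fold change (point) and quartiles (line) of the members of each of 40 gene lists at day 3 (red) and day 7 (blue) against sham, on the log2(FPKM + 1) scale; filled points passed the camera test with its preset correlation. The day 3 medians run from -3.28 to 2.53, and 5 lists are filled at day 7.

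At day 7 the injury and tubule genes fixed as a check of the labels did not differ from sham by the test, while other genes did. Havcr1, Lcn2, Cdkn1a and Slc34a1 were not called against sham (log2 fold changes -0.51 ± 1.35, -0.18 ± 0.75, -0.23 ± 0.40 and -0.39 ± 0.55 SE, adjusted p = 0.808, 0.884, 0.701 and 0.632). Hnrnpa3, which encodes an RNA-binding protein, was higher at day 7, at 0.28, 0.27 and 0.15 FPKM in sham and 21.14, 25.12 and 19.53 at day 7. Its day 3 libraries were at 35.41, 5.18 and 4.26 FPKM. The glycolytic enzyme gene Gapdh fell from 64.2 ± 17.5 to 18.9 ± 2.38 FPKM (log2 fold change -1.68 ± 0.20, adjusted p = 0.00152; corrected for the trend given next, -1.57, adjusted p = 0.0101). Whether reads of Hnrnpa3 and Gapdh also map to similar sequences elsewhere could not be checked, since the files hold no reads. In all, 4075 genes differed from sham, 2646 higher and 1429 lower, of which 564 by at least 2-fold (386 higher, 178 lower).

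Fold changes at day 7 went with the GC content of the transcript across genes, which are not independent replicates (Spearman rho = -0.66, and 0.39 with transcript length). In the lowest of 5 equal groups by GC content 1433 were higher and 15 lower than sham (median log2 fold change 0.54), and in the highest group 24 were higher and 773 lower (median -0.35). At day 3 the rho with GC content was -0.23. The day 3 median nonetheless fell from 0.60 in the lowest group (1566 higher, 302 lower) to 0.005 in the highest (743 higher, 741 lower). Within single libraries, deviations from the mean of each gene had a rho with GC content of 0.303 to 0.433 in sham, -0.0916 to -0.0273 at day 3 and -0.425 to -0.334 at day 7. After a smooth trend with GC content and length was removed from each library, 785 genes were called at day 7, 490 higher and 295 lower, and 614 of these were among the 4075. Of the 103 named genes called at day 7, 75 lost their call after this step, so corrected values are given beside the genes named below.

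**Figure D4:**
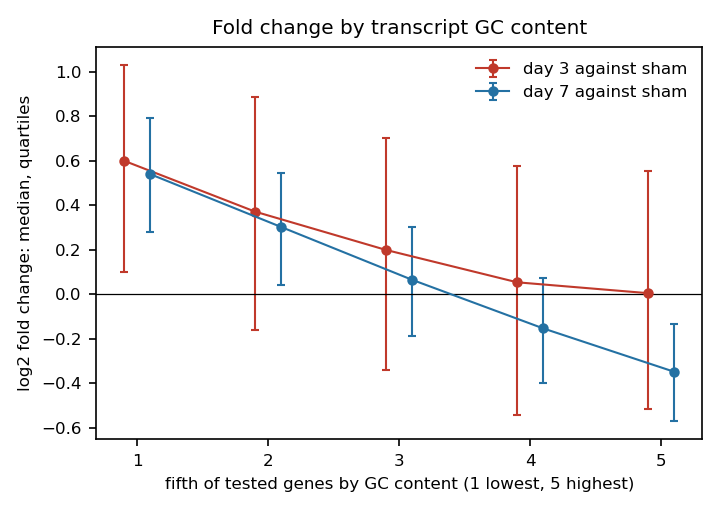
Median log2 fold change (point) and quartiles (error bar) against sham in 5 equal groups of tested genes ordered by transcript GC content, at day 3 (red) and day 7 (blue). The day 7 medians fall from 0.54 in the lowest group to -0.35 in the highest, and the day 3 medians from 0.60 to 0.005.

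The largest rises after Hnrnpa3 (4.21 ± 0.62, corrected 3.56, adjusted p = 0.0196) were of Idi1, Gatm, Sacm1l and Reps2. Sacm1l, a phosphoinositide phosphatase, kept its call (2.12 ± 0.20, corrected 1.59, adjusted p = 0.0101). Idi1, of isoprenoid synthesis (2.47 ± 0.63, corrected 2.03, adjusted p = 0.0983), Gatm, of creatine synthesis (2.35 ± 0.77, corrected 2.00, adjusted p = 0.156) and Reps2 (1.99 ± 0.36, corrected 1.33, adjusted p = 0.0784) did not. The largest falls were of Angptl4 (-2.49 ± 0.62, corrected -2.48, adjusted p = 0.0560), Gadd45g (-2.34 ± 0.41, corrected -1.72, adjusted p = 0.0565), Tmem252 (-2.16 ± 0.30, corrected -2.51, adjusted p = 0.0101), the immunoglobulin gene Igkc (-2.06 ± 0.65, corrected -1.85, adjusted p = 0.124) and Tmem37 (-1.78 ± 0.33, corrected -1.24, adjusted p = 0.0527). Without single libraries Gatm lost its call in 4 of 6 cases (adjusted p = 0.0674 without sham 2 and 0.0865, 0.119 and 0.118 without day 7 libraries 1, 2 and 3). Igkc lost its call without each day 7 library (adjusted p = 0.110, 0.113 and 0.0652), Idi1 without day 7 libraries 1 and 3 (adjusted p = 0.0505 and 0.0640) and Angptl4 without day 7 library 3 (adjusted p = 0.0629).

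Of the 40 lists 5 were called at day 7. Cytosolic ribosomal proteins were lower in 22 of 40 (23 over the list alone, median -0.43, camera adjusted p = 4.37e-09, and adjusted p = 0.991 with an estimated correlation). Rps16 was at -1.05 ± 0.15 (corrected -0.83, adjusted p = 0.0203), and after the trend was removed 6 of 40 were lower (median -0.20). Cholesterol synthesis and uptake genes were higher in 9 of 21 (10 over the list alone, median 0.44, camera adjusted p = 0.0257, and adjusted p = 0.991 with an estimated correlation). Hmgcs1 was at 1.30 ± 0.25 (corrected 0.87, adjusted p = 0.0689). The median of the cholesterol list against the sham mean was 0.45 to 0.55 in the day 7 libraries, and 0.44 in sham 2. Endothelial markers were lower in 2 of 18, antigen presentation genes in 1 of 14, and heat shock and immediate early genes in 4 of 21 (none, none and 3 over the list alone; medians -0.45, -0.56 and -0.40). The antigen presentation medians against the sham mean were -0.89, 0.06 and -0.89 in day 7 libraries 1, 2 and 3, and library 2 was the highest for 13 of 14 genes. The camera adjusted p was 0.0257 for each of these 3 lists, and adjusted p = 0.991 with an estimated correlation. Median-of-ratios scaling ended the call on heat shock and immediate early genes (adjusted p = 0.0715), and quantile normalization that call and the one on antigen presentation (MHC class I and II) (adjusted p = 0.0738 for both). Removing the trend ended the calls on antigen presentation (MHC class I and II) (adjusted p = 0.192) and on heat shock and immediate early genes (adjusted p = 0.304). Leaving out sham 1 ended those on cholesterol synthesis and uptake (adjusted p = 0.272) and endothelial markers (adjusted p = 0.0546), and leaving out sham 3 those on antigen presentation (MHC class I and II) (adjusted p = 0.246) and heat shock and immediate early genes (adjusted p = 0.422). Without day 7 library 1 antigen presentation (MHC class I and II) lost its call (adjusted p = 0.0585), and without day 7 library 3 every list but the ribosomal one did (adjusted p = 0.0829 for cholesterol synthesis and uptake and 0.0524 for the others).

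The tubule lists were not called. Proximal tubule transport had 6 of 37 genes higher and 3 lower and proximal tubule metabolism 2 of 34 higher and 5 lower (camera adjusted p = 0.956 and 0.0682). The list of proximal tubule metabolism was called without sham 1 (adjusted p = 0.00835) and without day 7 library 3 (adjusted p = 0.0357). Nat8 was still lower than in sham (-1.23 ± 0.22, corrected -0.95, adjusted p = 0.0499). Injury markers had 1 of 32 higher and 2 lower (none over the list alone) and p53 target genes 6 of 33 higher and 3 lower (camera adjusted p = 0.956 and 0.712). Day 7 library 2 was the highest of the 3 for 30 of 32 injury markers and 30 of 33 p53 target genes. Its median log2 difference from the sham mean was 0.71 for injury markers (0.02 and -0.32 in day 7 libraries 1 and 3) and 0.43 for p53 target genes (0.07 and 0.06). Over all tested genes the median of log2(FPKM + 1) was also highest in day 7 library 2 (2.54, against 2.41 and 2.36). Spp1 was at 551.74, 1809.51 and 575.54 FPKM in the day 7 libraries. The p53 target Ccng1 rose from 24.1 ± 1.76 FPKM in sham to 74.8 ± 30.5 at day 7 (1.53 ± 0.23, corrected 1.02, adjusted p = 0.0380). Oxidative phosphorylation had 6 of 40 higher and 10 lower (8 and 11 over the list alone), and the tricarboxylic acid cycle 5 of 20 higher and 1 lower (6 and 1 over the list alone), led by Sucla2 (1.32 ± 0.14, corrected 0.98, adjusted p = 0.0108). Gpx4 was lower than in sham (271 ± 18.9 FPKM, -0.99 ± 0.15), a call that ended after the trend was removed (corrected -0.36, adjusted p = 0.194). Mdm2 (0.60, corrected 0.37, adjusted p = 0.234) and Slc31a1 (0.46, corrected 0.02, adjusted p = 0.953) lost their calls after that step. Both also lost them without single libraries, Mdm2 without sham 2, sham 3 and day 7 libraries 2 and 3 (adjusted p = 0.115, 0.0584, 0.0917 and 0.0574) and Slc31a1 without each library but sham 3 (adjusted p = 0.0783 to 0.112). Spp1, Umod, Slc22a2, Ripk3, Mlkl and Col1a1 were not called (log2 fold changes 1.05, -0.26, -0.56, -0.12, 0.13 and 0.14, adjusted p = 0.139, 0.697, 0.0559, 0.547, 0.655 and 0.839), and Slc22a2 was called without sham 1 (adjusted p = 0.0201). Mki67 was at 0.5, 2.75 and 0.43 FPKM at day 7 and Slc7a11 at 0.09, 0.11 and 0.11.

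None of the 33 extracellular matrix and fibroblast activation genes was called by limma, and the count was also 0 when adjusted over the list alone. Median and mean were above 0 and the camera direction down for injury markers, proximal tubule transport, neutrophil markers, TNF and NF-kB response genes, apoptosis and extracellular matrix, none of them called.

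The libraries of day 7 and sham did not overlap for 48.7% of tested genes, against 10% by chance, and rescaling by the median of ratios gave 4472 calls, 2245 higher and 2227 lower. The count of 4075 became 2470 without sham 2 and 2696, 2699 and 2652 without day 7 libraries 1, 2 and 3.

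Between day 3 and day 7 the direction of most of these groups turned over. Krt20 fell from 650 to 1.92 ± 2.10 FPKM (log2 fold change -8.03 ± 0.41 SE, adjusted p = 4.39e-06), and Lcn2, Mt2 and Slpi were lower as well (log2 fold changes -6.89 ± 0.75, -5.87 ± 0.52 and -5.86 ± 0.12). G6pc rose from 3.11 ± 0.39 to 185 ± 66.8 FPKM (5.43 ± 0.61, adjusted p = 0.000136), and Tmem52b, Ugt2b37, Slc7a13 and Hsd3b2 rose by 5.38 ± 0.19, 5.34 ± 0.46, 4.94 ± 0.75 and 4.82 ± 0.68. In all, 7603 genes differed, 2977 higher and 4626 lower at day 7, and 3279 by at least 2-fold. Sprr2f was at 0.24, 0.82 and 0.18 FPKM at day 7. Havcr1, Cdkn1a, Mdm2, Spp1 and Ripk3 were lower (log2 fold changes -4.99, -5.47, -2.47, -3.33 and -2.01) and Umod and Slc31a1 higher (2.23 and 1.22). Col1a1 (-0.41, adjusted p = 0.478) and Gpx4 (0.22, adjusted p = 0.235) were not called, but Gpx4 was called under median-of-ratios scaling (adjusted p = 0.0463), after removal of the GC content trend (adjusted p = 0.00498) and without day 3 library 1 (adjusted p = 0.0221).

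All 37 proximal tubule transport genes were higher at day 7 than at day 3 (37 adjusted over the list alone, median 2.95, camera adjusted p = 7.01e-19, and adjusted p = 0.301 with an estimated correlation). Slc34a1 was at 4.40 ± 0.55 and Slc22a2 at 3.51 ± 0.19. Proximal tubule metabolism had 28 of 34 higher and 1 lower (camera adjusted p = 1.20e-12, and adjusted p = 0.301 with an estimated correlation). Thick ascending limb markers were higher in 13 of 14, distal convoluted and connecting tubule markers in 12 of 14, intercalated cell markers in 11 of 16 and principal cell markers in 9 of 14. Egf was at 4.04 ± 0.45, Calb1 at 4.61 ± 0.57, Rhcg at 3.99 ± 0.25 and Hsd11b2 at 2.74 ± 0.64. These 4 lists were called (camera adjusted p = 1.21e-07, 1.19e-06, 2.69e-07 and 0.00124, and adjusted p = 0.301, 0.301, 0.407 and 0.459 with an estimated correlation). Oxidative phosphorylation was higher in 32 of 40, the tricarboxylic acid cycle in 18 of 20, fatty acid oxidation and peroxisome in 16 of 41 with 3 lower, and the mitochondrially encoded genes in 10 of 13 with 1 lower (camera adjusted p = 6.05e-11, 6.95e-10, 0.00121 and 0.000731, and adjusted p = 0.301, 0.301, 0.491 and 0.459 with an estimated correlation). Cholesterol synthesis and uptake was higher in 13 of 21, erythrocyte genes in 5 of 6 and cisplatin transport and detoxification in 9 of 16 with 5 lower (camera adjusted p = 1.91e-05, 0.00386 and 0.0222, and adjusted p = 0.459, 0.407 and 0.407 with an estimated correlation). The last of these calls was lost under median-of-ratios scaling (adjusted p = 0.0798) and with quantile normalization (adjusted p = 0.0855), which also ended that on mitochondrially encoded genes (adjusted p = 0.178).

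Most lists called higher at day 3 were called lower at day 7 than at day 3. Among their genes, this held for 28 of 32 tubule injury and repair markers, 28 of 33 p53 target genes and all 6 tested neutrophil markers (camera adjusted p = 1.21e-07, 4.20e-10 and 0.0142, and adjusted p = 0.430, 0.407 and 0.459 with an estimated correlation). All 40 cytosolic ribosomal proteins were lower, as were 25 of 30 proteasome genes, 16 of 21 heat shock and immediate early genes with 1 higher, and 14 of 23 NRF2 target genes with 1 higher (camera adjusted p = 1.20e-12, 1.27e-05, 2.01e-05 and 0.00818, and adjusted p = 0.412, 0.412, 0.412 and 0.522 with an estimated correlation). Apoptosis genes were lower in 18 of 26 with 3 higher, interferon-stimulated genes in 21 of 25, TNF and NF-kB response genes in 13 of 16 with 1 higher, chemokines and cytokines in 11 of 17 with 2 higher, and necroptosis and pyroptosis in 9 of 16 with 1 higher (camera adjusted p = 0.00120, 2.61e-05, 0.00132, 0.0192 and 0.0497, and adjusted p = 0.459, 0.459, 0.470, 0.491 and 0.494 with an estimated correlation). The lists of chemokines and cytokines and of necroptosis and pyroptosis had not been called at day 3. DNA replication genes were lower in 11 of 23 and higher in 1 (10 and 1 over the list alone). The DNA replication list was not called (camera adjusted p = 0.0959), but was without day 7 library 2 (adjusted p = 0.0129). The call on necroptosis and pyroptosis was lost without day 3 libraries 1 and 3 (adjusted p = 0.0824 and 0.0506) and without day 7 libraries 1 and 3 (adjusted p = 0.0684 and 0.0550). Adjusted over the list alone, the counts moved by at most 2 genes in each called list. Cd68 fell from 98.5 ± 13.7 to 2.61 ± 1.33 FPKM (-4.84 ± 0.24), and Cxcl1 and Mlkl had log2 fold changes of -4.42 ± 0.51 and -2.59 ± 0.20.

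Of the 8214 genes called at day 3, 5693 (69.3%) changed back between day 3 and day 7, 125 moved further in the same direction and 2396 did not differ between the 2 days by the test. Both tests use the same 3 day 3 libraries, so chance values in them favour a change back over a move further. The count of 125 became 19 after the GC content and length trend was removed. It became 71 without sham 2, 50 and 58 without day 3 libraries 2 and 3, and 67, 67 and 62 without day 7 libraries 1, 2 and 3. Among the genes that changed back, 4383 were not called against sham at day 7, 825 were still displaced in the day 3 direction and 485 lay beyond sham on the other side. Another 1259 genes were called at day 7 and not at day 3, which does not by itself show that the days differ for them. After the same trend was removed, the counts of 4383, 825, 485 and 1259 were 5985, 180, 100 and 227, and 6265 of 7838 genes changed back.

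Both cisplatin groups were compared with the same 3 sham libraries, which alone makes their fold changes correlate. The correlation across genes was 0.273, against 0.502 in simulated unchanged groups, and the covariance was 0.148 against 0.0283, a difference of 0.120. The share of genes with the same sign was 62.8%, against 66.8% in the simulation. The simulated r and share follow from the shared sham libraries alone. Real changes widen the spread of fold changes and can lower both. That the observed r and share lay below the simulated ones thus does not show less agreement than in unchanged groups. Genes higher at both days numbered 1702, against 1039 for independent lists of these sizes. Genes lower at both numbered 629, against 294. After the GC content and length trend was removed, 312 were higher at both days against 179, and 146 lower against 60.6. Part of the excess may come from the shared controls, since 3 sham libraries cannot be split into 2 sets of at least 2.

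The libraries of day 7 and day 3 did not overlap for 64.4% of tested genes, against 10% by chance, and 25 of 40 lists were called (13 up, 12 down), none with an estimated correlation. Rescaling by the median of ratios moved the median of all genes by 0.14 (log2) and the split of calls from 2977 higher and 4626 lower to 3742 higher and 3744 lower.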

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

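The tests on long protein-coding genes, on other macrophage markers and on the ribosomal list after GC correction were chosen after the result was seen. The changes from sham at day 3 and day 7 differed, by the test of day 7 against day 3, in 7603 genes, in 25 gene lists and in 175 of the named genes. Of the genes called at both days, 240 were higher than sham at day 3 and lower at day 7. Another 245 were lower at day 3 and higher at day 7. Independent lists of these sizes would give 561 and 545, so opposite genes were fewer than for independent lists. The shared sham libraries favour changes in the same direction. Of these 485 opposite genes, 69 were among the 100 found after removal of the GC content and length trend. Called lists of opposite direction were heat shock and immediate early genes (median log2 fold change 2.00 at day 3 and -0.40 at day 7), cholesterol synthesis and uptake (-0.37 and 0.44) and cytosolic ribosomal proteins (0.75 and -0.43). With an estimated correlation none of the 3 was called (adjusted p = 0.558, 0.605 and 0.569 at day 3, and 0.991 for each at day 7). The day 7 call on heat shock and immediate early genes ended after the trend was removed (adjusted p = 0.304), under median-of-ratios scaling (adjusted p = 0.0715), with quantile normalization (adjusted p = 0.0738), and without sham 3 (adjusted p = 0.422) or day 7 library 3 (adjusted p = 0.0524). That on cholesterol synthesis and uptake ended at day 3 without sham 2 (adjusted p = 0.0834), and at day 7 without sham 1 (adjusted p = 0.272) or day 7 library 3 (adjusted p = 0.0829). The medians of this list against the sham mean were -0.47, 0.44 and 0.11 in sham libraries 1, 2 and 3. They were -0.42, -0.39 and -0.37 at day 3, and 0.45, 0.55 and 0.53 at day 7. The day 3 medians thus lay within the sham range, and sham 2 lay close to day 7, so the opposite directions rest on sham libraries that disagree.

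With 10 splits of 6 libraries into 3 and 3, the splits are too few for a share under 0.05. The real split called 8214, 4075 and 7603 genes for day 3 against sham, day 7 against sham and day 7 against day 3, the highest other split called 2 in each, and 1 of the 10 splits, the real one, reached each value. For gene lists the real splits called 25, 5 and 25, the highest other splits 24, 25 and 29, and 1, 10 and 4 of the 10 splits reached the real value. At day 7 another split thus called 25 lists and at most 2 genes. Of 100 splits of the 9 libraries into 3 groups, 1, the real one, reached 5693, the count of genes that changed at day 3 and back by day 7. The highest other split gave 4779 and also kept the 3 day 3 libraries together. Both contrasts behind the count use those libraries, so it can be large wherever they stand apart from the rest. The splits thus show that day 3 stands apart, and cannot decide whether day 7 returned toward sham.

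The day 7 fold changes fell with the GC content of transcripts across genes. Genes of a common function followed the same trend, with a median rho of -0.68 within the 18 lists of at least 20 tested members (-0.87 to -0.32), as a GC content or length bias of the libraries predicts. Reads of pseudogenes and short RNAs are argued against, since rho was -0.71 in 11105 protein-coding genes with a longest transcript of at least 1000 nt. A GC content bias may therefore account for much of the count of 4075, which was 785 after the trend was removed. The trend goes with the group in every sham and day 7 library and the labels give no batch, so a change in the tissue that acts by GC content stays open and untested.

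Cd68 (chromosome 11, 69664213 to 69666153) rose by 4.21 at day 3 while the 16 other tested macrophage markers had no common rise. Chil3 (5.54) and Cd14 (3.36) rose too, and 4 of the 17 were higher in all. The 16 other markers had a median of 0.050 and an upper quartile of 0.857, below the lower 95% bound for Cd68 of 3.74. This argues against a common rise of all macrophage and monocyte markers as the whole cause. Cd68 was among the largest rises of the list, so most others were likely to lie below it. With 4 of the 17 higher and 4 lower, the pooled values cannot decide on changes in single kinds of these cells. The adjacent gene Eif4a1 (69666936 to 69672423, same strand) had a log2 fold change of 1.34 and Mpdu1, on the other side, -0.06. The value of 1.34 lies between the bounds set for shared signal and for none. A constant share of Eif4a1 signal is argued against, since Cd68 rose by 4.21 ± 0.24 SE and Eif4a1 by 1.34 ± 0.13 SE. A share that changed by day 3 cannot be told apart from a rise of Cd68 itself, because the files hold no reads. Expression of Cd68 in other cells of the injured kidney stays open as a hypothesis that was not tested.

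Cytosolic ribosomal protein genes were lower at day 7 than in sham (median -0.43, SD over genes 0.293). After removal of the GC content and length trend the median was -0.20 (SD 0.296), and 6 of 40 were lower in place of 22. The list was still called by camera with its preset correlation (adjusted p = 7.02e-06). That call cannot show that the pattern outlasts the trend. The correlation estimated for this list before the trend was removed was 0.637, and none was estimated after it. Another split of the day 7 and sham libraries also called 25 lists with the preset correlation. The trend may account for part of the pattern, and whether it accounts for the whole stays open. Reads that moved to processed pseudogenes are argued against, since 108 ribosomal protein pseudogenes had a median of -0.40. Reads shared by genes and pseudogenes would lower both together, so this value cannot decide on sharing as such. Before the trend was removed, the list was not called by camera with an estimated correlation (adjusted p = 0.991). A lower demand for ribosomes at day 7 stays open as a hypothesis that was not tested.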

How the results depend on the processing

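The corrections for GC content and length, the feature classes, quantile normalization of the lists and the leaving out of libraries for the time course and agreement were chosen after seeing the data. Named genes were recomputed under the pseudocount, both scalings, robust variance, 6 libraries alone, the replicate block, GC correction and leave-outs, and not under the filters or the 2-fold minimum. Of 127 called at day 3, at most 4 lost their call under any one of these, and of 125 for day 7 against day 3 at most 8. Of 103 called at day 7 against sham, 75 lost their call after GC correction, 45 in some leave-out of a library, 16 with the 6 libraries alone, 11 under median-of-ratios scaling and 0 with robust variance. Calls fell from 8214 to 5104 (day 3) and from 7603 to 4973 (day 7 against day 3) at the 5 FPKM filter, and returning genes from 5693 to 3755, with fewer genes tested. With a 2-fold minimum, which can only lower a count, they were 3631, 564 and 3279. GC correction left 785 calls and 3 lists at day 7, and r between the responses at 0.206; the cause was not tested. Leaving out each library gave 2470 to 3760 calls and 2 to 6 lists at day 7, with fewer samples, and r of 0.209 to 0.346; the cause of the last was not tested. With the correlation estimated per list, 0 lists were called at day 3, 0 at day 7 and 0 for day 7 against day 3, and fry, a test of another hypothesis, called 32, 0 and 32. Signs turned under GC correction for Uty at day 3 (-0.0158) and for Rrm1 (-0.0183), Ercc6 (-0.0303) and Sod2 (-0.184) at day 7; the cause was not tested. With the replicate block the counts were 8212, 3885 and 7540, and 26, 5 and 25 lists were called, against 25, 5 and 25 without it. Libraries of the same number deviated with r of -0.05 to 0.24, and not every library correlated best with its own number, so the numbers were not taken to pair the samples. Depth limits are unknown without counts.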

Other observations

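Circadian clock genes moved apart. Of 17 tested, 9 were higher and 4 lower at day 3 (camera adjusted p = 0.757, not called), and 2 higher and 2 lower at day 7 (adjusted p = 0.636, not called). The clock repressor gene Per1 rose from 4.59 ± 0.491 to 20.99 ± 5.18 FPKM at day 3 (SD, n = 3). It was at 1.43 ± 0.315 FPKM at day 7 (log2 fold change against sham -1.21 ± 0.18, corrected for GC content -0.92, adjusted p = 0.0319). Hlf, an output transcription factor of the clock, fell from 6.71 ± 1.55 to 0.687 ± 0.171 FPKM at day 3 and was at 12.3 ± 1.72 at day 7 (0.80 ± 0.17, corrected 0.35, adjusted p = 0.266). The hours at which the kidneys were taken are not given.

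Few lymphocyte markers were expressed enough to be tested, 2 of 20 for T and NK cells and 3 of 13 for B and plasma cells. Both tested T and NK cell markers fell, Trac from 2.83 ± 1.21 to 0.240 ± 0.0361 FPKM and Trbc2 from 1.32 ± 0.587 to 0.0167 ± 0.0289 FPKM. Of the B cell and plasma cell markers 2 fell, Igkc and Ighm (log2 fold changes -2.46 ± 0.65 and -2.26 ± 0.34). Igkc was at 4.15, 4.52 and 32.37 FPKM in the sham libraries. At day 7 neither T and NK cell marker was called and 1 B cell marker was, Igkc. Of 5 adipose and adrenal tissue markers Cidec and Fabp4 were higher at day 3 (3.28 ± 0.44 and 1.72 ± 0.27; list camera adjusted p = 0.283) and none at day 7 (0.815). Of 6 skeletal and smooth muscle markers none was called at day 3 (median 0.13, and -0.06 under median-of-ratios scaling; camera adjusted p = 0.934). At day 7 1 of them, Cnn1, was lower (-0.48 ± 0.16, corrected -0.37, adjusted p = 0.196; list adjusted p = 0.0682, and 0.0241 without sham 2, for skeletal and smooth muscle markers).

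Day 7 library 2 stood apart from the other day 7 libraries in several lists, which were looked at after their values were seen. It was the highest of the 3 for 31 of 33 extracellular matrix and fibroblast activation genes, 25 of 25 interferon-stimulated genes, 16 of 17 macrophage and monocyte markers, 18 of 18 endothelial markers and 39 of 40 cytosolic ribosomal proteins. Over all tested genes its median of log2(FPKM + 1) was 2.54, against 2.41 and 2.36 in day 7 libraries 1 and 3. These values were not rescaled, so a higher scale of library 2 may account for part of these counts. The share over all tested genes was not computed. Day 7 library 2 was the highest for 5 of 37 proximal tubule transport genes and 0 of 6 erythrocyte genes. Members of a list do not vary independently, and no cause was tested.

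Y-linked genes were read as a check of the samples. Ddx3y stood at 2.96, 1.66 and 1.73 FPKM in sham, 7.13, 7.35 and 6.52 at day 3, and 5.73, 8.01 and 5.13 at day 7. Eif2s3y stood at 5.6, 4.59 and 3.33 FPKM in sham, 18.31, 13.94 and 11.7 at day 3, and 11.13, 11.44 and 10.62 at day 7. Of 4 tested genes of this list 3 were higher at day 3 and 4 at day 7. After the GC content and length trend was removed 2 were called at day 3, Eif2s3y (1.20, adjusted p = 0.000522) and Ddx3y (1.001, adjusted p = 0.00186), and Uty was at -0.0158 (adjusted p = 0.910). None was then called at day 7 by limma, with 0.61 for Eif2s3y (adjusted p = 0.0805), 0.58 for Ddx3y (adjusted p = 0.104) and 0.20 for Uty (adjusted p = 0.301). Xist was between 0 and 0.13 FPKM in every library.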
